A study of Caenorhabditis elegans with 2 samples.

How the data were processed

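Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the chromatin remodeller CHD-3 in adult Caenorhabditis elegans of the fem-2(b245) strain, which carries a mutant allele of the sex determination gene fem-2. The series holds 2 samples, 1 immunoprecipitate (ChIP) and 1 input DNA library, and both carry the replicate number 2 in their labels. Per the labels' protocols, frozen worms were ground, fixed with 1% formaldehyde for 10 minutes and sonicated, and CHD-3 was recovered with an affinity-purified rabbit polyclonal antibody. Libraries were amplified by PCR after size selection. The culture temperature given by the submitters was 20 °C. The labels give the stage as young adult with a germline, while the growth protocol describes the harvest of gravid adults.

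The deposited file analysed here is a list of peaks of the ChIP sample. Per the file header and its source column, the peaks were called by MACS and lie on WormBase release WS220. Per the submitters' processing notes, BWA was used and the genome build was ce10. The MACS and BWA versions, the read filters, the calling threshold, the control used for calling and any pooling of libraries are not given in the sources used here. Each peak has a first and last base, counted from 1, and a score. The score deposited by the authors has no named scale in the file. Its lowest value was 50, and 111 peaks shared the value 3100. The score was used to rank and filter peaks within this list and to compare median scores. Ranks among the tied peaks carry no information. Pearson's r and the sizes of differences in score depend on the unnamed scale. The tie may mark the limit of the scale, so whether the 2 values above 3100 rank above or below the tied peaks is not known. Read counts, read depth and fold enrichment per peak were not used here, so the sequencing depth is unknown and no counting interval could be given for any peak. No signal of the input library was analysed here, so no value below has a background measured in input DNA beside it.

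The gene table at hand is of assembly WBcel235. Since the peaks lie on WS220, gene positions were not compared with peaks, and the tests planned for gene starts, parts of genes, gene biotypes, gene lists, base composition and GAGA repeats were not run. For the same reason no gene is assigned to any peak. Chromosome lengths of WS220 were not used here either. Each chromosome was taken to run from base 1 to the last base of its last peak, which gave spans that add up to 100.1 Mb, and lengths, densities and positions below refer to these spans.

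The tests were planned before the data were examined, except where the text says otherwise. Counts per chromosome were compared with counts proportional to span by Pearson's chi-square, with p from 100000 multinomial draws. The share of peak midpoints in the central 50% of each chromosome was compared with 10000 circular rotations of that chromosome's peaks, which keep the spacing of the peaks. The share of neighbouring midpoints within 2000 bp of each other was compared with 10000 uniform placements of as many midpoints per chromosome. The relation of score and width across peaks was given as Spearman's rho and Pearson's r, and scores on X and autosomes were compared as medians, each with 100000 permutations. The rotations and placements are permutation tests of position. All p-values are two-sided except those of the chi-square, of the number of chromosome starts in a peak and of the fullest window, which are one-sided for large values. The 6 planned tests form one family, and Benjamini-Hochberg adjusted values are given beside the raw ones. Peaks within 1 list are not replicates, so these p-values describe the layout of this list and say nothing of how it would vary between cultures. Shares of peaks have 95% exact (Clopper-Pearson) intervals, which cover counting error only and treat peaks as independent.

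The peaks named by rule are the 10 with the highest score, with ties broken by width, and the 5 widest. The runs of close peaks, the densest windows and the peaks at chromosome starts were chosen after their values were seen. The alternatives were the 50% of peaks with the highest score, merging of peaks less than 500 bp apart, leaving out the chromosome with most peaks per Mb, the central 33.3% in place of the central 50%, and neighbour distances of 1000 and 5000 bp. The tests of counts per chromosome, of the central share of autosomal peaks, of clustering, of score and width, of scores on X and of widths by position were tested on simulated data with the peak number of this list. All 20 of the simulated lists with a known effect were called by each of these tests. Apart from the planted effect, the simulated peaks were drawn independently, without the uneven density of this list. Each effect was planted at a single size. These calls therefore do not give the power or the error rate of the tests on this list. The central share of X alone, the chromosome starts and the windows were not simulated. Of 20 lists without an effect, 2 were called by the clustering test, 2 by the chromosome test and 0 by the other tests simulated. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.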

Results

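The genomic distribution of CHD-3 was mapped by ChIP-seq in hermaphrodite fem-2(b245) adults grown at 20 °C. CHD-3 is a C. elegans relative of Mi-2, the ATPase of NuRD-type nucleosome remodelling and deacetylase complexes. The labels name 1 ChIP library and 1 input DNA library, and the peak list deposited for the ChIP sample was analysed. It has no replicate here and whether it pools libraries is not stated, so the comparisons are between parts of the genome within 1 list. The read depth behind the list is unknown. The question addressed was where along the chromosomes CHD-3 was recovered.

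The list held 4940 peaks on the 5 autosomes and X. Together they covered 2.60 Mb, which was 2.60% of the chromosome spans. Most peaks were narrow, with a median width of 327.5 bp and an interquartile range of 234 to 543 bp, and the narrowest measured 102 bp. A minority was broad. The 474 peaks of 1000 bp or more were 9.60% of the list and made up 36.8% of the covered length, and 26 of them spanned at least 5000 bp. The deposited score had a median of 116 and an interquartile range of 72.3 to 242.0. It was tied at 3100 for 111 peaks, and 2 peaks had higher values, which may not be stronger than the tied ones.

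Chromosome IV carried the densest set of CHD-3 peaks and chromosome V the sparsest. On IV there were 1072 peaks, or 61.3 per Mb, against 863.2 expected from its span, a ratio of 1.24. Chromosome III had 773 peaks at 56.1 per Mb, 1.14 times its expected number, and chromosome I had 797 at 52.9 per Mb, 1.07 times. Chromosome II had 671 peaks at 44.2 per Mb, a ratio of 0.895. Chromosome V had 857 peaks at 41.04 per Mb, 0.83 times the expected 1030.4. The X chromosome held 770 peaks at 43.5 per Mb, which was 15.6% of the list (95% exact interval 14.6 to 16.6%) where its span was 17.7% of the total. The counts differed from proportionality by more than multinomial sampling allowed (chi-square 116.6, 5 degrees of freedom, p = 1e-05, the smallest that 100000 draws can give, adjusted p = 3e-05 over 6 tests). Neighbouring peaks are not independent, which makes that p too small. When peaks less than 10000 bp apart were chained into 1 region, an alternative chosen after seeing the data, IV still had 1.18 times and V 0.88 times its expected number of regions (chi-square 29.9, p = 2e-05). The chained regions are still treated as independent there. Density also varied over longer stretches, from 8 to 138 peaks per Mb in 500 kb bins, so that p can be too small as well.

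**Figure D1:**
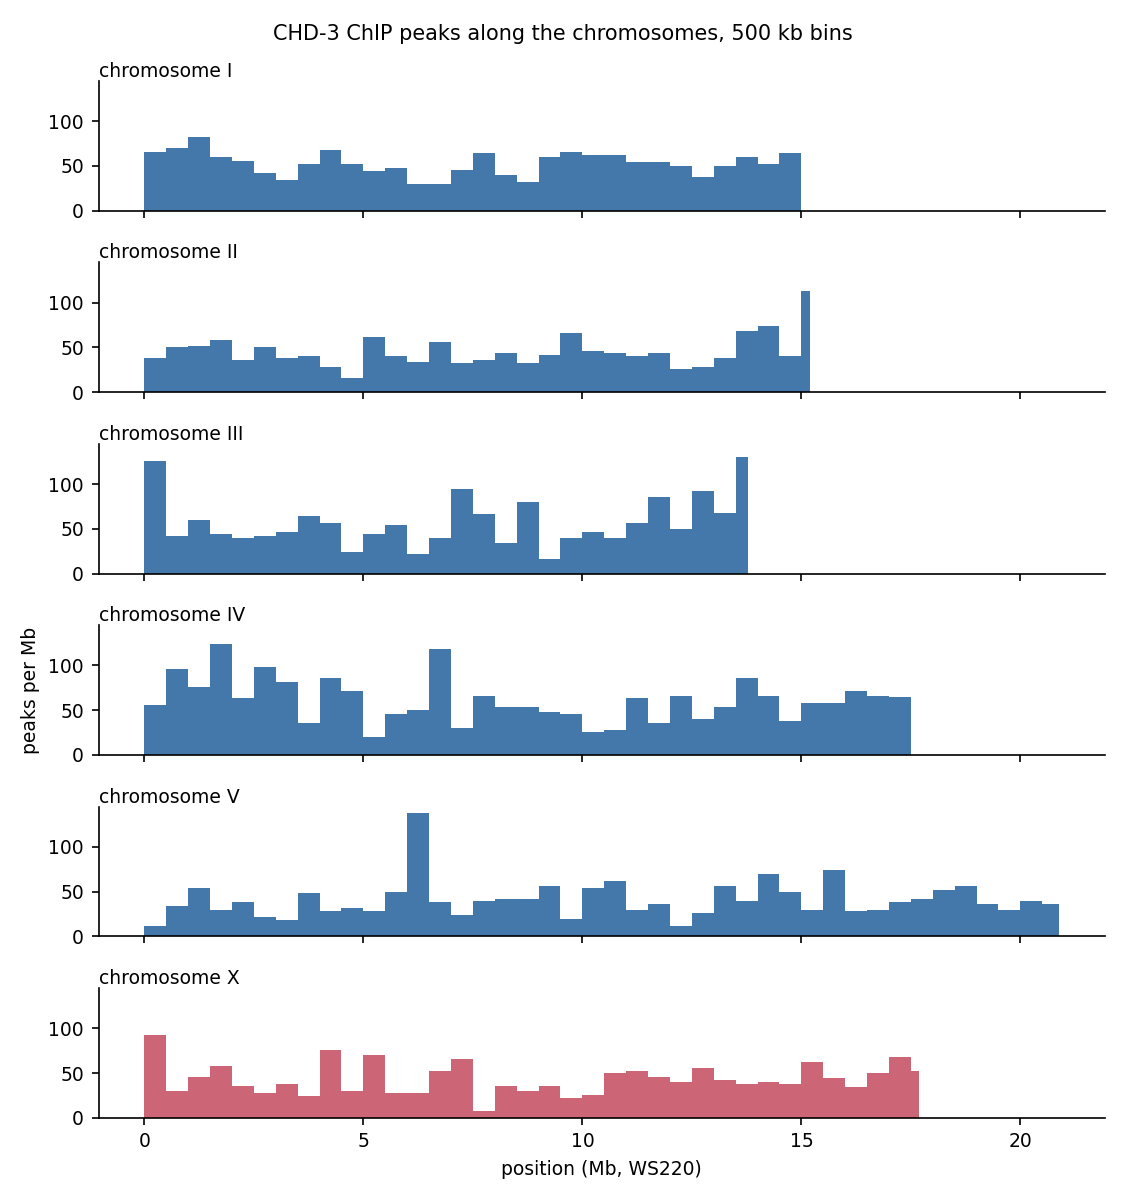
Peaks per Mb in 500 kb bins along the 5 autosomes (blue) and X (red), by position on WS220 in Mb. Bars are counts of the 1 ChIP list divided by bin length, and bins under 0.1 Mb at right ends are not drawn. The highest bin, 138 peaks per Mb, lies at 6.0 Mb of chromosome V, and the lowest, 8 per Mb, at 7.5 Mb of X.

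Peaks were found both in the centres and in the arms of all chromosomes. In C. elegans the autosome arms recombine more and are richer in repeats than the centres, so the central share was examined. On the autosomes 1976 of 4170 midpoints, or 47.4%, lay in the central 50% of the spans, against 49.98% in the rotated lists (95% of rotations 45.9 to 54.1%, permutation p = 0.27, adjusted p = 0.40). Among the 2470 peaks with the highest scores the sign turned, with 50.2% of the autosomal midpoints in the centre (0.25 points above the rotations, permutation p = 0.91). On X the central share was 45.2% of 770 peaks against 49.99% (95% of rotations 43.2 to 56.8%, permutation p = 0.34, adjusted p = 0.40). Among single chromosomes the share was lowest on IV, at 42.7%, and highest on V, at 56.4%. Neither differed from its rotations after adjustment over the 6 chromosomes (adjusted permutation p = 0.62 for IV and 0.33 for V). The tests of single autosomes were not planned and are not in the family of 6 planned tests, and IV and V are named as the extremes. A shift of a few percentage points was not detectable with this number of peaks and this degree of clustering.

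CHD-3 peaks occurred in groups. Of 4934 neighbouring pairs, 1837 or 37.2% had midpoints within 2000 bp of each other, 3.88 times the 9.59% of uniform placement (95% of placements 8.82 to 10.4%, permutation p = 0.0001, the smallest the placements can give, adjusted p = 0.0002). In 1387 pairs, 28.1% of all, the peaks themselves were less than 500 bp apart, and in 414 less than 50 bp. Merging peaks less than 500 bp apart left 3553 regions, of which 2742 were single peaks, 811 joined several peaks and 263 joined 3 or more. Of the merged regions 11.9% still had the next midpoint within 2000 bp, against 6.98% of uniform placement (permutation p = 0.0001). Merging peaks less than 1000 bp apart, chosen after seeing the data, turned the excess to -3.08 percentage points. That merging removes nearly all such neighbours by construction. Within 5000 bp it left an excess of 2.08 points (permutation p = 0.0002). Uniform placement lacks the uneven density of the list, which ran from 8 to 138 peaks per Mb in 500 kb bins. Such variation over long stretches can by itself raise the share of close neighbours. The p-values of clustering can therefore be too small, and the small excesses after merging do not show local grouping.

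**Figure D2:**
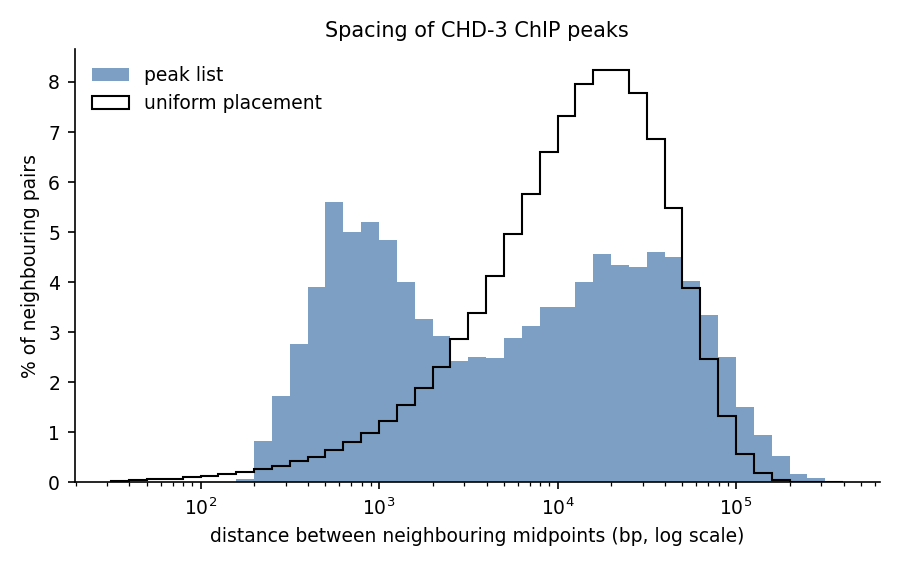
Distance between neighbouring peak midpoints in bp (log axis) as a percentage of all neighbouring pairs, for the 4940 peaks (blue) and for 100 uniform placements of as many midpoints per chromosome (black line). The list has a group of short distances around 1000 bp that uniform placement lacks, 37.2% of pairs lying within 2000 bp.

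The most extended runs of close peaks lay on III, X, V and IV. The longest, on chromosome III from 7405325 to 7443078, joined 20 peaks over 37.8 kb, of which 97.2% was inside peaks, and its peaks had a median width of 1277.5 bp and a median score of 753. On X a run from 4026012 to 4056447 joined 14 peaks over 30.4 kb with 97.6% of it covered and a median score of 1106. On V a run from 6070782 to 6094654 joined 31 peaks, the most of any run, over 23.9 kb. Its peaks were narrower, with a median of 510 bp, and 83.4% of it was covered. On IV a run from 6710185 to 6729290 joined 13 peaks over 19.1 kb with 97.2% covered. Counted in 100 kb windows, the median window held 4 peaks, and the fullest windows were 6000001 to 6100000 of V with 35 peaks, 300001 to 400000 of III with 33 and 7400001 to 7500000 of III with 27. In 1000 uniform placements no window held more than 21 peaks, and 5 windows of the list exceeded that (permutation p = 0.001 for the fullest window, the smallest the placements can give). Those placements do not keep the grouping of close peaks, which can by itself give fuller windows. The window on III at 7400001 had 45.3 kb inside peaks and a median peak score of 721, whereas the window on III at 300001 had 12.7 kb and a median score of 87.7.

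**Figure D3:**
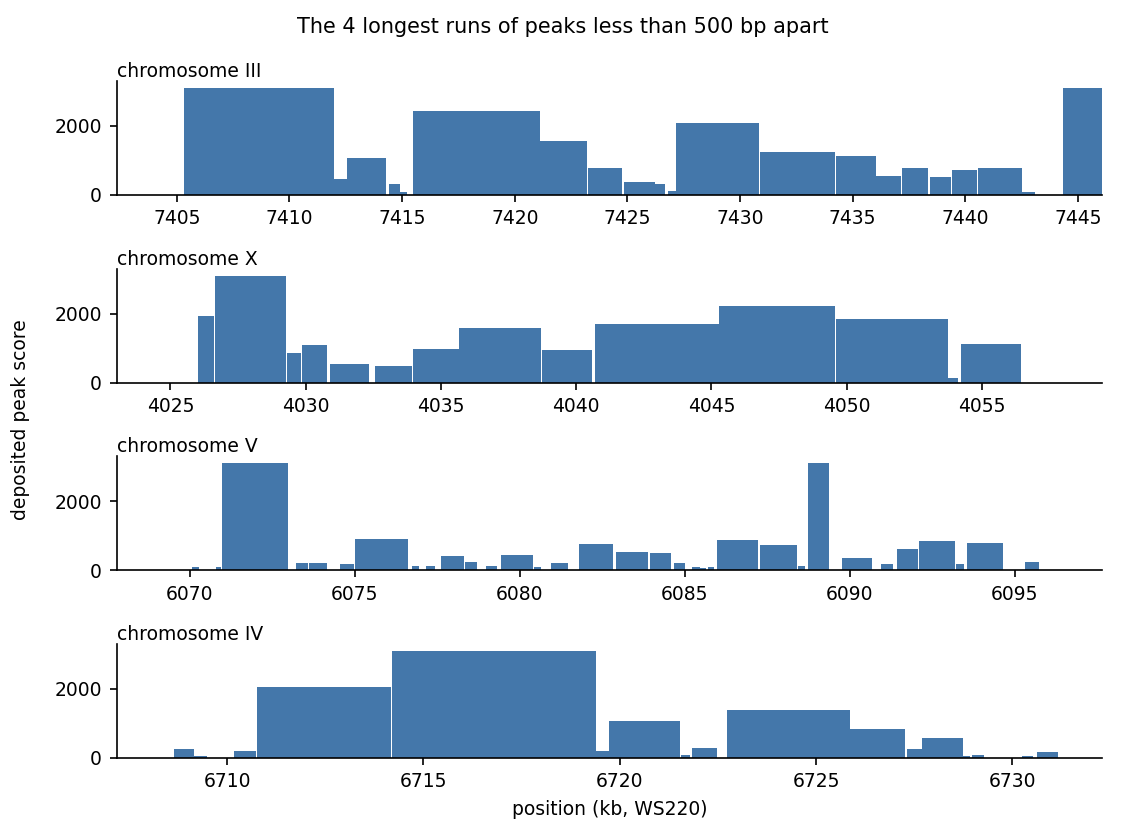
The 4 longest runs of peaks less than 500 bp apart, drawn by position on WS220 in kb with 3000 bp on each side. Each bar is 1 peak, as wide as the peak and as high as its deposited score, which is tied at 3100. Peaks fill 97.2% of the run on III, 97.6% of that on X and 97.2% of that on IV, and 83.4% of the run on V.

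Broad peaks had the higher scores. Across the 4940 peaks score and width rose together (Spearman's rho 0.88 and Pearson's r 0.75, p = 1e-05 for each, the smallest that permutations can give, adjusted p = 3e-05). Peaks are not independent replicates. The scale of the score is not named, and a score that grows with the reads a peak collects would rise with width at equal enrichment, so the relation does not show stronger enrichment at broad peaks. The median width was 203 bp in the 1235 peaks with the lowest scores and 844 bp in the 1235 with the highest, and peaks of 1000 bp or more were 37.98% of the 1235 highest-scoring and 0% of the 1235 lowest-scoring. Without the peaks scored 3100 or more, an alternative chosen after seeing the data, rho was 0.87.

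**Figure D4:**
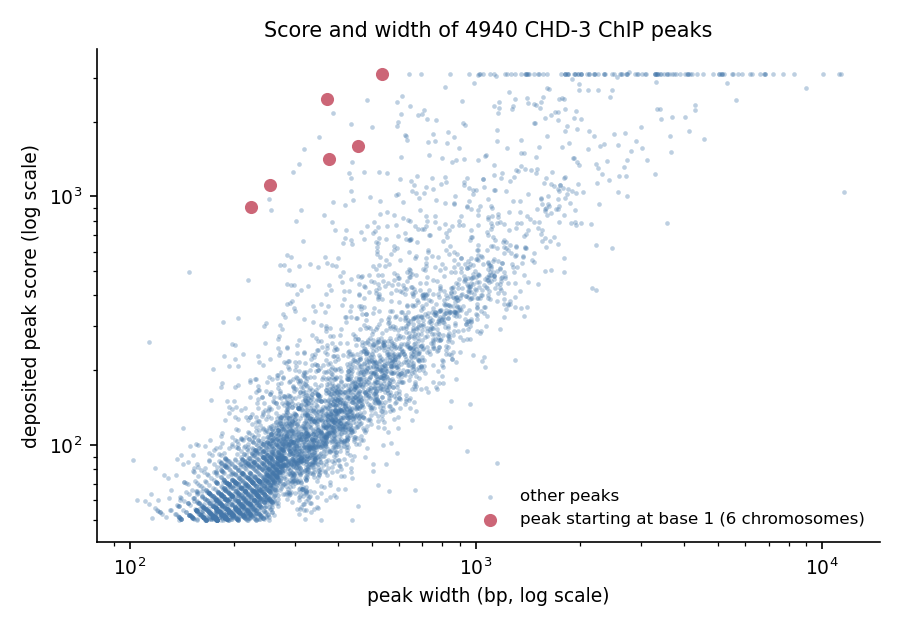
Deposited score against width in bp of each of the 4940 peaks, both on log axes. The horizontal line of points at the top is the value 3100 shared by 111 peaks. Red points are the 6 peaks that begin at base 1 of a chromosome, which score between 910.0 and 3100.

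Among the 5 widest peaks 4 lay on chromosome I. The widest ran from 4345316 to 4356880 (11565 bp, score 1043). The next were 10207999 to 10219292 (11294 bp), 15060214 to 15071353 (11140 bp) and 10266300 to 10276355 (10056 bp), all scored 3100. The fifth was on II from 3159605 to 3168558 (8954 bp, score 2717). The peak at 15060214 was the last of chromosome I, whose right end carries the tandem array of ribosomal RNA genes in C. elegans. Whether the peak covers that array was not tested here. The 10 peaks highest by the deposited number, in which the place of the 2 values above the tie is uncertain, were 14835487 to 14838256 of II (score 3174), 16100075 to 16101174 of X (score 3114) and the 8 widest of those tied at 3100. These 8 included 3 of the widest peaks on I just given. The other tied peaks were 7916818 to 7925077 of V (8260 bp), 6566780 to 6574491 of III (7712 bp), 10945889 to 10953099 of I (7211 bp), 10605659 to 10612490 of V (6832 bp) and 17119885 to 17126706 of V (6822 bp).

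Peaks on X and on the autosomes had close median scores. The median was 116.7 for the 770 X peaks and 115.9 for the 4170 autosomal peaks, a difference of 0.805 for X minus autosomes (p = 0.86 by permutation, adjusted p = 0.86). The sign of this difference turned when close peaks were merged, where it was -6.515 (permutation p = 0.32), and when chromosome IV was left out, where it was -0.16. The median width was 348 bp on X and 325 bp on the autosomes, a difference of 23 bp (p = 0.021 by permutation, not planned and not in the family of 6). That permutation treats neighbouring peaks as independent, which can make its p too small, and chromosome II had a median of 355 bp, above that of X. X held 25 of the peaks scored 3100 or more, V 24, I 23, III and IV 15 each and II 11.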

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

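Of the alternatives to the results, those chosen after seeing the data were the chaining at 10000 bp, the merging at 1000 bp, the removal of tied scores, dense windows or single autosomes, and all those for widths by position and for chromosome starts. No paired analysis was possible because the input library has no values here and each group holds 1 sample. In 36 of the 40 alternatives that have a test the direction and the side of the threshold stayed as reported, and in 4 the direction turned. The 36 include results that were not past the threshold and stayed so. They also include the counts per chromosome, where a chi-square has no direction that could turn. For the central share of X, leaving out the dense windows removed none of the 770 peaks, so nothing could change. For the clustering it removed too few pairs to bring the share near that of uniform placement. With the 50% of peaks with the highest score, 2470 peaks remained by construction, covering 1.98 Mb, and the central share of autosomal peaks minus the rotated share turned from -2.59 to 0.25 percentage points, neither past the threshold (permutation p = 0.27 and 0.91). Over the other alternatives of that share the difference stayed negative, from -4.98 percentage points without chromosome V to -0.99 without chromosome IV. Their permutation p ranged from 0.051, without chromosome V, to 0.65. The difference in score between X and autosomes turned to -6.515 with close peaks merged and to -0.16 without chromosome IV, with p of 0.32 and 0.98. The excess of neighbours within 2000 bp over uniform placement turned from 27.6 to -3.08 percentage points when peaks less than 1000 bp apart were merged, since that merging removes nearly all such neighbours by construction. With the same merging and neighbours within 5000 bp it was 2.08 points (permutation p = 0.0002), an excess that uneven density along the chromosomes could also give. The tests that need gene positions or sequence were not run, so their alternatives were not run either. Depth could not be examined.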

Other observations

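The tests of chromosome starts, of widths by position, of the densest windows and of windows without peaks were chosen after the data had been seen, and merging, although planned, was turned into a test of grouping only then. The sequence of every chromosome began inside a peak. The peaks starting at base 1 ended at base 536 on I, 455 on II, 224 on III, 254 on IV, 376 on V and 372 on X, and their scores ran from 910.0 on III to 3100 on I. Their median score was 1508, against 116 for all other peaks (difference 1392, permutation p = 0.00036), and only 21 of the 2598 other peaks of 224 to 536 bp scored as high as the lowest of them. Chromosome ends in C. elegans carry telomeric repeats.

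A hypothesis is that CHD-3 chromatin was enriched at chromosome starts. Chance placement is argued against, as none of the 10000 rotations put all 6 starts in a peak (permutation p = 0.0001, the smallest they can give, with a mean of 0.15 starts). A general rise of peak density toward the left ends was not seen, since the first 50000 bp held 16 other peaks where rotations gave 15 (95% of them 5 to 31). That range is wide, so a moderate rise cannot be excluded. An effect of sequence ends on the caller or on read mapping, including repeats that are more numerous in the worm than in the assembly, stays open: 1 of the 6 last peaks scored at least as high as the lowest first peak, but whether the last peaks touch the right ends is not known from the list. The last peak that did so was that of chromosome I, 11140 bp wide where the first peaks had 224 to 536 bp. The other last peaks scored 59.65 to 530.28. Without an input track the biological and technical explanations cannot be told apart.

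The grouping of peaks may in part be a matter of listing, since 57.8% of the 474 peaks of 1000 bp or more had a neighbour less than 500 bp away against 43.1% of the others. Splitting of single stretches with gaps under 500 bp as the whole cause is argued against, as 11.9% of merged regions had the next within 2000 bp against 6.98% of uniform placement, although the excess shrank from 27.6 to 4.95 percentage points. Uneven density could give part of that remainder. Splitting with wider gaps stays open. Merging peaks less than 1000 bp apart turned the excess to -3.08 points, but that merging removes nearly all such neighbours by construction. Without the 10 densest windows 4692 of the 4934 pairs remained, and the share was 35.5%, so most close pairs lay outside those windows. Removing so few pairs could not have brought the share near that of uniform placement. This therefore decides nothing about dense regions in general. Real grouping of CHD-3 sites stays open, as does any uneven mappability or input signal along the genome.

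Autosomal peaks were wider in the central 50% of the chromosomes, with a median of 356.5 bp for 1976 peaks against 298 bp for 2194 peaks outside (difference 58.5 bp, permutation p = 0.0002 with widths shifted along each chromosome), and the difference was positive on all 5 autosomes. Taken alone and without adjustment, only III had a p under the threshold (100.5 bp, permutation p = 0.010), while the others gave 30 to 76 bp with p from 0.088 to 0.31. These p-values were not adjusted over the chromosomes, so they do not establish a difference on III by itself. Wide peaks of a single chromosome are argued against as the cause, since the highest p with an autosome left out was 0.0025. Splitting of stretches with gaps under 500 bp is argued against by a difference of 73 bp after merging. An excess of weak, narrow calls outside the centre stays open: the central share was 50.2% among the 50% of peaks with the highest score against 47.4% of all, and the 71.5 bp within that 50% decides nothing, because score and width go together (rho 0.88). On X the difference was 6 bp (permutation p = 0.91), but the autosomal and X differences were not shown to differ (52.5 bp, p = 0.17). A dependence of CHD-3 domain width on chromosome position is a hypothesis, and differences in mappability or gene density between centres and arms were not tested and may account for it.

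The longest stretch without a peak ran over 272.3 kb of II from 10560087 to 10832418, followed by 264.2 kb of I from 6195294 and 263.4 kb of V from 12038881. The longest distance between neighbouring midpoints, 273.8 kb, lay within the range of 1000 uniform placements, whose longest had a median of 191.6 kb and a maximum of 330.1 kb. Of 1002 windows of 100 kb, 61 held no peak, where 1000 uniform placements gave 9.09 on average and at most 20. The placements scatter peaks independently, so the grouping of peaks can by itself leave more windows empty. The empty windows are therefore not a separate finding. Among the 113 peaks scored 3100 or more, 108 were at least 1000 bp wide. The 5 narrower ones were the start of I, 6088744 to 6089385 and 17115403 to 17116097 of V, 3896942 to 3897785 of III and 142775 to 143726 of X.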
